A study of Mus musculus with 4 samples.

How the data were processed

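Liver RNA of wild-type and Fto knockout mice on a C57/Bl6 background was measured in an immunoprecipitate made with an antibody against methylated adenosine and in the matching input. The labels describe 4 samples in 4 groups (wild-type and knockout, immunoprecipitate and input), and each label states 3 replicates. miCLIP crosslinks the antibody to RNA and clones the bound fragments by the iCLIP procedure. The antibody recognises N6-methyladenosine as well as N6,2'-O-dimethyladenosine (m6Am), the form found next to the cap. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase.

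What was deposited are comparison tables made by the authors, 1 for the immunoprecipitate by transcript identifier and 1 for the input by gene identifier. STAR, bedtools 2.25.0, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, with no role or parameter for any of them. Per the file headers, each feature has the authors' mean normalized signal over the libraries, which is an average of scaled read counts. It also has the authors' log2 fold change with its standard error on the log2 scale, a test statistic (unit score, per the file headers), and a p-value with its adjusted p-value as the authors computed them. Counting rules, model formula, library sizes and filters were not given in the sources used here. Genomic coordinates were not used here. Values of single replicates were not analysed here, so depth per library is unknown, and no replicate could be compared with another or left out. The labels do not say whether replicates were separate animals, so p-values measure the spread between these samples, which may be technical.

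The deposited statistics were checked before use. In the input table the statistic equalled the log2 fold change over its standard error, the Wald form. Standard errors there did not exceed 0.302, and the fold changes have the small sizes of shrunken estimates. In the immunoprecipitate table the p-value was the upper tail of a chi-square distribution with 1 degree of freedom at the statistic. That statistic was not the squared ratio of fold change to standard error (Spearman 0.823 across features). The authors' p-value there is therefore not the Wald test of the printed fold change. Whether it tests that fold change in another way or another term is not given in the sources used here. Nor is what else the model held, or which contrast the fold change stands for. Fold changes in that table are not shrunken. Neither header states the direction. The input was read as knockout over wild type because Fto was lower. The immunoprecipitate was read the same way, and that reading rests on a weak positive correlation with the input. From the lowest p-value and its adjusted value, the authors adjusted over 3799 features in the immunoprecipitate, where 2347 have an adjusted value and 6846 a p-value. Going by their p-values and adjusted values, the called features there do not fill every rank, so some called features lie outside the table. In the input the authors adjusted over 14167 genes, more than the 12883 in the table, so genes outside it entered the adjustment.

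Features were called changed where the authors' adjusted p was under 0.05. Gene names were taken from the table itself and brought to current symbols, with 12869 of 12883 input gene identifiers matched. In the immunoprecipitate 183 features had no match. An earlier naming of immunoprecipitate features through gene identifiers gave Ugt1a10 transcripts the name of another gene of the Ugt1a cluster, whose exons they share. It was replaced after its results had been seen and is kept as an alternative. List membership was likewise narrowed to current symbols after a first look. Named features were chosen by a rule fixed before the data were examined: Fto, snRNAs with a symbol of their own, up to 10 called rises and 10 called falls per table at a mean of at least 10, the 5 highest and 5 lowest ratios of the difference between the tables to its standard error, and up to 4 members of each list described, those with the lowest p. Of the genes this rule named, 2 are not reported here.

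The design fixed before the data were examined listed snRNA genes by symbol and by family name, with copies and pseudogenes set apart as an alternative. The immunoprecipitate table gives only family names, so every feature the table names as a family was used there and, for the same treatment, in the input, where genes with their own symbol became the alternative. Copies of a family are near identical, and reads could be split between them by the authors' counting, so values of single copies are uncertain. The design also assumed a Wald statistic. For the immunoprecipitate the signed normal quantile of the authors' p was used in its place.

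Each of 34 fixed gene lists with at least 3 measured features was tested with cameraPR of limma 3.58.1 in R 4.3.3 against the other features of its table, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 65 tests of both tables. A correlation could not be estimated without single replicates, so preset values of 0.05 and 0.1 were tried. A list's median was ranked among 10000 random lists of its size matched on mean level. Sm-class and U6-class snRNAs were compared by two-sided permutation of class labels over copies, with 100000 permutations. The difference between the tables was the difference of the log2 fold changes over the root of the summed squared standard errors, for genes at a mean of at least 10 in both, with 1 immunoprecipitate feature per gene, a normal p and Benjamini-Hochberg adjustment. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with seed 1.

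Alternatives covered the threshold, the minimum mean, the centring of fold changes, the correlation within lists, rank-based list tests, copies against 1 feature per family, and the statistic. The scripts were tested on simulated data. For the difference between the tables, run on 748 genes, 28% of changes of log2 size 4 and 85% of size 8 were recovered, and 2.6% of calls were false. A shifted list was called in each table, and 0 of 30 unshifted lists in the immunoprecipitate and 0 of 33 in the input. The simulated fold changes had normal errors of exactly the printed standard error, and the simulated list statistics were independent between features. These rates therefore test the scripts and do not give the share of false calls in the deposited values.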

Results

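Fto encodes a demethylase of methylated adenosines in RNA, and the series asks whether methylation of small nuclear RNAs (snRNAs) depends on it. The immunoprecipitate table held 7569 features with means from 0.120 to 34539 (median 4.92), of which 1682 had a mean of at least 10. The input table held 12883 genes with means up to 414332 (median 26.1). Means are the authors' normalized values, and the tables were normalized separately. snRNAs made up 55.2% of the summed means in the immunoprecipitate table and 0.103% in the input table. These shares are not alike, since the first is summed by transcript and the second by gene. Reads of near-identical copies may enter the first more than once: U1 copies had means of 19547, 19552 and 19557 with nearly 1 fold change.

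Fto was the gene with the lowest p in the input. The direction of the input comparison was itself read from Fto, so its sign is no separate result. In the input, the authors' deposited table gave Fto a log2 fold change of −1.49 (SE 0.27, adjusted p = 3.52e-04, mean 55.8). Fto was not among the immunoprecipitate features analysed here.

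Immunoprecipitated RNA was compared between knockout and wild-type liver to ask which RNAs were bound more or less by the antibody without Fto. Directions are given as knockout over wild type, a reading that rests on a weak correlation with the input; read the other way, every sign in the immunoprecipitate turns. U1, the snRNA that recognises the 5' splice site, had the most called copies. Of its 77 copies, 19 were called higher in the authors' deposited table, and the most abundant copy had a log2 fold change of 4.50 (SE 0.49, adjusted p = 0.00333, mean 34539). U5, which holds the exons during splicing, had 1 called copy at 3.75 (adjusted p = 0.0169), and U4atac of the minor spliceosome reached 3.45 (SE 0.59, adjusted p = 0.0274) in the authors' deposited table. These 21 snRNA copies were all of the higher calls among the deposited features. Lower calls numbered 89, among them 67 protein-coding, 20 snoRNA, 1 7SK and 1 5S rRNA features. Some features called by the authors lie outside the deposited ones, so calls of unknown direction are missing from these counts. The 10 largest called rises were U1 copies, with log2 fold changes from 4.02 to 5.12 in the authors' deposited table.

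The called falls sat on less abundant features than the called rises. At such means a fitted fold of this size rests on very few reads in a group, so falls are not ranked against rises by size. Called falls had a median log2 fold change of −9.11 at a median mean of 19.6, against a median mean of 5720 for called rises, from the authors' deposited table. Among the 10 largest falls there, 4 were transcripts of Ugt1a10, a glucuronidating enzyme gene, between −11.81 and −11.20 in the authors' deposited table. Ugt1a10 had 8 called transcripts, which share exons with other genes of the cluster and are not independent. The splicing factor gene Srsf2 stood at −11.37 (SE 1.76, adjusted p = 0.00149) in the authors' deposited table. Aplp2, a relative of the amyloid precursor, stood at −11.32 and Rbm14 at −11.21 (adjusted p = 5.27e-05) in the authors' deposited table. The snoRNAs snoR38 and SNORD83 were both at −11.11 in the authors' deposited table.

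The median feature with a mean of at least 10 stood at −0.82 in the immunoprecipitate, so directions near 0 depend on the scaling. That median lies on a value shared by 842 features, and without repeated values it was −1.03. Calls made from fold over standard error, in place of the authors' p, numbered 213 higher and 606 lower, and centring those folds gave 284 and 376. Sm-class snRNA features were 67 of the 213 higher and 76 of the 284. With 1 feature per gene or family, 2 were higher and 60 lower by the authors' p. Of the calls in the authors' deposited table, 19 higher and 8 lower had a mean of at least 50. The contrast behind the printed fold change and the term behind the authors' p are not given in the sources used here, which limits how a fold and its p can be read together.

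Sm-class snRNAs, which carry a trimethylguanosine cap and a ring of Sm proteins, were set against U6-class snRNAs, which have another kind of cap and no Sm ring, in the immunoprecipitate. Across copies with a mean of at least 10, all 52 U1 copies lay above 0, with a median of 3.90 and a range from 1.94 to 6.52 in the authors' deposited table. Medians there were 1.32 for U2 (16 copies), 2.33 for U4 (9 copies), 3.53 for U5 (7 copies), 1.78 for U11 (2 copies) and 3.36 for U12 (3 copies) in the authors' deposited table. U6 (24 copies) had a median of −0.80, which is 0.02 above the median feature, and ranged from −10.02 to 5.29 in the authors' deposited table. U6atac stood at −0.38 before and 0.44 after centring, in the authors' deposited table.

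As a list, the 137 Sm-class features rose in the immunoprecipitate. Their median log2 fold change was 3.28, which is 4.87 above the median of all features, with 21 called higher and 28 adjusted over the list alone (limma camera adjusted p = 4.87e-45). The median lay at percentile 100 of the random lists, and the call held at a correlation of 0.1 (adjusted p = 3.46e-07). Near-identical copies may be correlated beyond that preset value, so both list p-values may be too small. The 160 U6-class features did not pass (adjusted p = 0.893), with 0 called and 0 adjusted over the list alone. Their median of −0.82 is the value shared by 842 features, and it lay 0.77 above the median of all features and at percentile 99.99 of the random lists, so the percentile does not set the classes apart. The medians of the classes differed by 4.10, and by 4.17 without features at repeated values, each with a permutation p of 1e-05, the smallest these permutations can give. Copies are not independent, so this p is too small. The classes were not matched on mean, which reached 203 for U6 and 34539 for U1. With 1 copy per family the 7 families had a median of 3.36 (adjusted p = 2.91e-11). Of these copies only those of U1 and U4atac were called by the authors. Those of U5 (3.53), U12 (3.36), U4 (2.54), U11 (2.23) and U2 (1.01) were not, in the authors' deposited table.

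**Figure D1:**
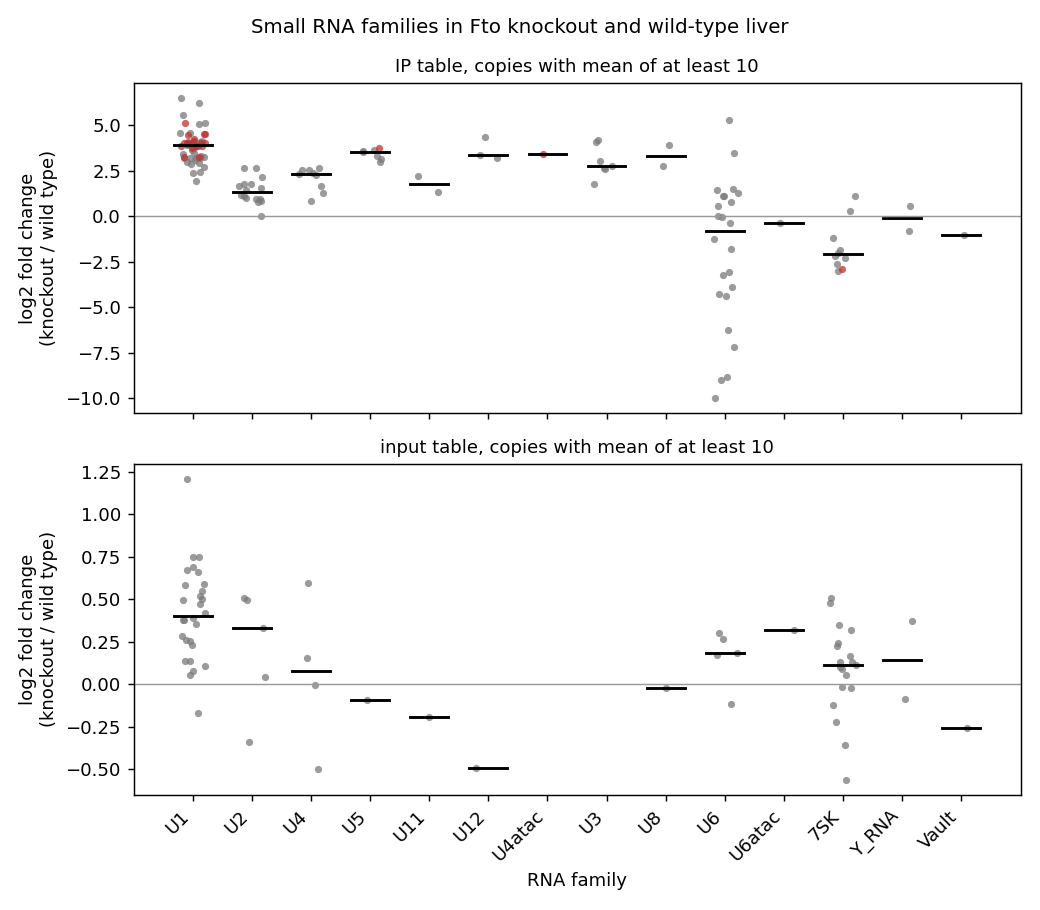
Log2 fold changes of small RNA families, knockout over wild type as read here, for copies with a mean of at least 10 in the immunoprecipitate table (top) and the input table (bottom, on a smaller scale). Points are copies, bars are family medians and red points have an authors' adjusted p under 0.05; the U1 median lies at 3.90 in the immunoprecipitate and 0.40 in the input.

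The other lists that passed in the immunoprecipitate went down. The snoRNAs and scaRNAs, which guide modification of ribosomal and small nuclear RNA, fell as a list of 283 features by the list test. Their median of −1.35 lay 0.24 above that of all features, so the median and the test differ in sign against that reference, while among random lists matched on mean it lay at percentile 1.61. In it 17 were called lower and 27 adjusted over the list alone (limma camera adjusted p = 0.0121), and the call ended at a correlation of 0.05 (adjusted p = 0.401). SNORA7 stood at −10.04 (SE 1.33, adjusted p = 6.26e-07), SNORA4 at −9.75, SNORA55 at −8.64 and SNORD37 at −7.87 in the authors' deposited table. Genes of fatty acid oxidation and targets of the lipid receptor PPARA fell as a list of 23 features (median −1.82, limma camera adjusted p = 0.0384). The median of all features was −1.59, so this median lay at −0.23 from it, at percentile 16.92 of the random lists. That call ended at a correlation of 0.05 (adjusted p = 0.229) and with 1 feature per gene (adjusted p = 0.0608). Ppara itself stood at −10.47 (SE 1.65) and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, at −9.63 (SE 1.64) in the authors' deposited table. These were 2 called features, and 3 passed adjusted over the list alone.

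Lists that did not pass still held single falls. Cytosolic ribosomal protein genes had 6 called lower and 8 adjusted over the list alone among 64 features (limma camera adjusted p = 0.567), with Rps9 at −9.00, Rpl34 at −9.04 and Rps25 at −7.17 in the authors' deposited table. Of the 6, 3 were Rps9 transcripts with nearly the same fold change, which are not independent. Saa4, an apolipoprotein of the serum amyloid A family, stood at −10.56 and Mlxipl, a regulator of lipogenic genes, at −7.60 in the authors' deposited table. Among 22 features of other RNA polymerase III transcripts 1 7SK copy was lower, at −2.91 (adjusted p = 0.0341) in the authors' deposited table. Of 31 lists tested in the immunoprecipitate 3 passed.

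**Figure D2:**
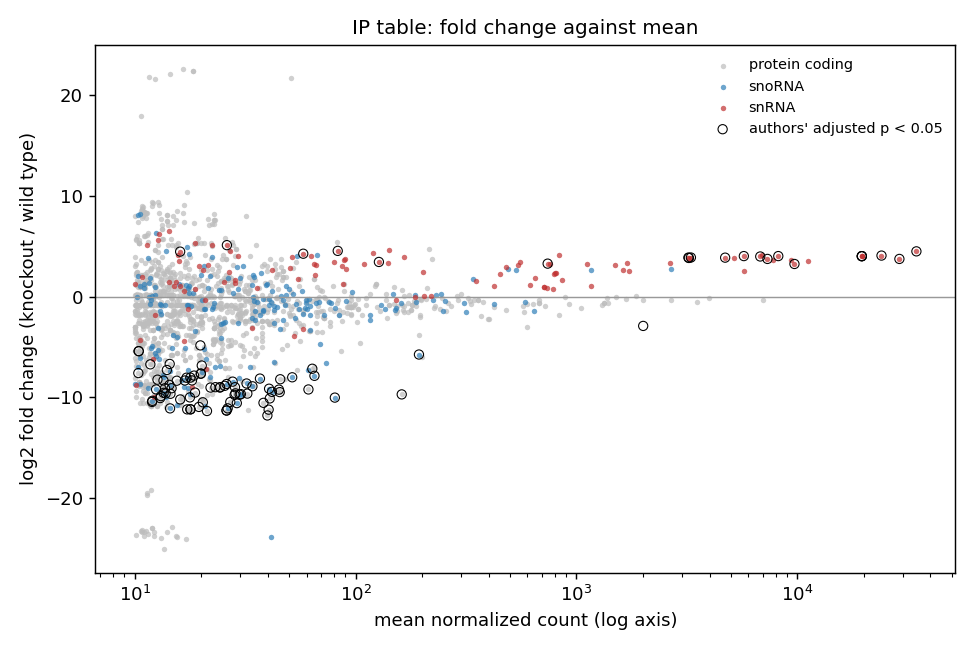
Log2 fold change in the immunoprecipitate, knockout over wild type as read here, against the authors' mean normalized value on a log axis, for protein-coding, snoRNA and snRNA features with a mean of at least 10. Circles have an authors' adjusted p under 0.05; the called rises have a median mean of 5720 and the called falls of 19.6.

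Input RNA was compared between knockout and wild-type liver to ask which RNA levels differed. There were 5 genes past the threshold in the authors' deposited table, 3 higher and 2 lower. The ubiquitin ligase gene Trim36 rose by 1.36 (SE 0.28, adjusted p = 0.00484) and Serpina7, which encodes thyroxine-binding globulin, by 1.32 (SE 0.27, adjusted p = 0.00484) in the authors' deposited table. The carboxylesterase gene Ces1b rose by 1.08 (SE 0.24, adjusted p = 0.0313), and the predicted gene Gm10382 stood at −1.29 (SE 0.30, adjusted p = 0.0453) beside Fto in the authors' deposited table. Ces1b has close paralogs that could share its reads. An unadjusted p under 0.05 was reached by 284 genes.

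Shifts of gene lists in the input were small, on the shrunken scale. The 19 male-biased liver genes fell (median −0.17, limma camera adjusted p = 4.72e-05, 2 of them above 0), with 0 called and 0 adjusted over the list alone. Cyp2d9, a steroid hydroxylase gene, was at −0.66 (SE 0.28) and Mup3, a urinary pheromone carrier gene, at −0.62 (SE 0.28) in the authors' deposited table. This call held at a correlation of 0.1 (adjusted p = 0.0454). The labels give no sex for the mice. Female-biased genes did not pass (median 0.08, adjusted p = 0.373), nor did 4 sex-marker genes, all of the Y chromosome (median −0.02, adjusted p = 0.893). Ddx3y stood at 0.23, Uty at 0.19, and Eif2s3y and Kdm5d at −0.23 in the authors' deposited table, at means from 47.4 to 123. Male tissue was thus among the livers, and these genes give no sign of a sex difference between the groups. The list of 5 genes around Fto on its chromosome passed with Fto in it (adjusted p = 0.000683) and not without it (4 genes, median −0.18, adjusted p = 0.483). Of these neighbours, Rpgrip1l was at −0.61 and Chd9 at 0.33 in the authors' deposited table.

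Markers of macrophages and Kupffer cells rose in the input as a list of 18 (median 0.33, limma camera adjusted p = 0.00147, 11 above 0). H2-Ab1, an antigen-presenting class II gene, stood at 0.96 (SE 0.29) and was the 1 member past the threshold adjusted over the list alone, with Fcer1g at 0.79 in the authors' deposited table. The call held at a correlation of 0.05 (adjusted p = 0.0277) and ended at 0.1 (adjusted p = 0.143). Cell-cycle genes rose beside these markers (22 genes, median 0.23, adjusted p = 0.0121, and 0.136 at a correlation of 0.05), with Top2a at 0.66 (SE 0.30), Mki67 at 0.59 and the inhibitor gene Cdkn1a at −0.63 in the authors' deposited table, and 0 passed adjusted over the list alone. Secreted hepatocyte proteins fell (28 genes, median −0.17, adjusted p = 0.00492, and 0.107 at a correlation of 0.05), with Apoe at −0.37 (SE 0.21) and 0 adjusted over the list alone in the authors' deposited table. Markers of endothelial cells (adjusted p = 0.893), stellate cells (adjusted p = 0.893) and lymphocytes (adjusted p = 0.688) did not pass. Erythroid and neutrophil markers did not pass as a list (median −0.43, adjusted p = 0.151), though Alas2, the heme synthesis enzyme gene of red cells, passed adjusted over the list alone at −0.99 (SE 0.29) in the authors' deposited table.

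Cholesterol synthesis genes rose (22 genes, median 0.18, limma camera adjusted p = 0.0194), with Lss, the lanosterol synthase gene, at 0.45 (SE 0.28) in the authors' deposited table, and 0 adjusted over the list alone. Xenobiotic-metabolising enzyme genes rose as a list of 40 (median 0.11, adjusted p = 0.0121), with members on both sides. Cyp2c54 and Cyp2c37, both at 0.92, and Cyp2f2 at −0.75 passed adjusted over the list alone in the authors' deposited table. Mitochondrially encoded genes rose (23 genes, median 0.17, adjusted p = 0.0317), with 0 adjusted over the list alone. The cholesterol, xenobiotic and mitochondrial calls all ended at a correlation of 0.05 (adjusted p = 0.183, 0.223 and 0.229). The bile acid enzyme gene Cyp8b1 at −0.84 (SE 0.25) and the insulin-repressed gene Igfbp1 at 0.94 (SE 0.30) passed adjusted over the list alone in the authors' deposited table, in lists that did not pass.

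**Figure D3:**
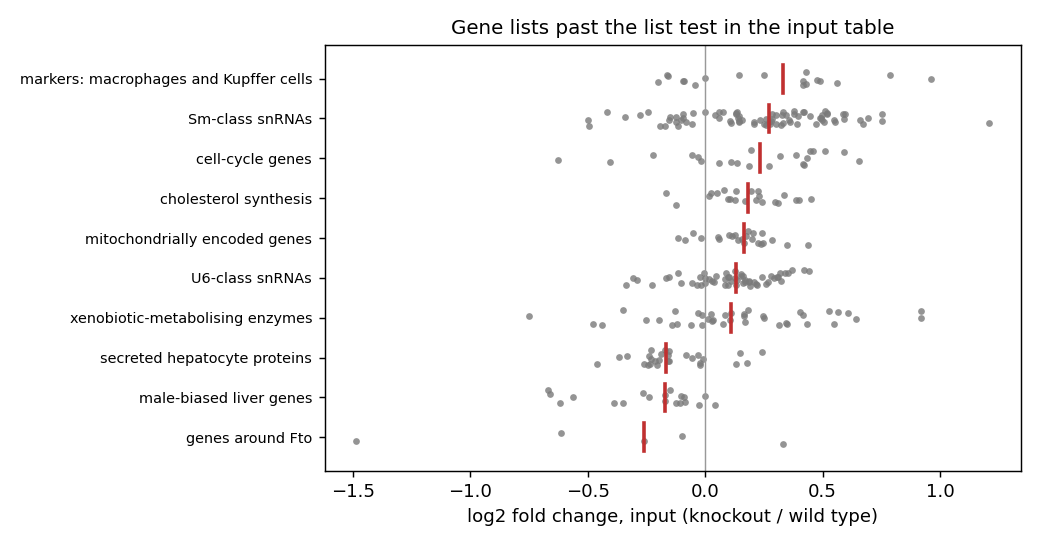
Input log2 fold changes of the members of the 10 gene lists past the list test at a preset correlation of 0.01. Points are genes or snRNA copies and red bars are list medians, from −0.26 for genes around Fto to 0.33 for macrophage and Kupffer cell markers; 4 of these calls held at a correlation of 0.05, and the call on genes around Fto ended without Fto.

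Sm-class snRNAs also rose as a list in the input when every copy was used. The 81 copies had a median of 0.27 (limma camera adjusted p = 2.63e-08), with 0 called and 1 adjusted over the list alone. The call ended at a correlation of 0.1 (adjusted p = 0.0960). The pair of genes with their own symbol, used as the alternative without copies, went the other way, with a median of −0.34 and no list test. Rnu11 stood at −0.19 (SE 0.28) and Rnu12 at −0.49 (SE 0.29), neither past the threshold, in the authors' deposited table. U6-class snRNAs rose as well (56 copies, median 0.13, adjusted p = 0.0204, 0.287 at a correlation of 0.05), with 0 adjusted over the list alone. The classes differed by 0.14 (permutation p = 0.00381), and at a mean of at least 10 by 0.14 (permutation p = 0.375).

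Immunoprecipitate and input changes were then compared per gene. Across 748 genes measured at a mean of at least 10 in both tables, the fold changes correlated weakly (Spearman 0.165, permutation p = 2e-05; Pearson 0.124, permutation p = 0.00065). This is a correlation across genes, which are not independent replicates. It is also the support for reading both tables in the same direction. The difference between the tables passed for 200 genes, 44 higher and 156 lower in the immunoprecipitate, and 248 had an unadjusted p under 0.05. With the immunoprecipitate direction turned, 206 passed, 166 higher and 40 lower. Only 5 genes passed at a minimum mean of 50 in both, 1 higher and 4 lower. The test of the difference takes the errors of both tables as independent, though the input is the matching one. It also rests on the printed immunoprecipitate standard error, by which 819 features were called. The authors' p called 110 with their own adjustment, and 34 when adjusted over all features with a p. Of the 200, 19 had immunoprecipitate fold changes beyond 15 in size, which are not measurable sizes at these means, and 39 were also called in the authors' deposited table, all lower. Shrinkage in the input alone narrows its fold changes, so the difference in part compares estimates of different kinds, and if the printed immunoprecipitate fold already allowed for the input, the input would be subtracted again.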

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

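The tests of few reads and RNA level given here were all chosen after the results were seen, while the difference between the tables and its named genes were planned.

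Immunoprecipitate and input changes of the same gene differed, by a test of the difference itself, for the genes the rule named by the ratio of difference to standard error, of which 9 protein-coding genes are given. These are fitted values and not measured sizes: log2 changes of this size cannot be resolved at immunoprecipitate means between 11.3 (Csrp2) and 50.9 (Hpd), so neither the size nor the test of the difference can be read at face value. The fitted immunoprecipitate change lay above the input change by 21.56 for Hpd, a tyrosine breakdown enzyme gene, by 22.30 for Acsm1, 21.98 for Slc1a2, 21.68 for Gtpbp4 and 22.71 for Pfdn1. It lay below the input change for Copa (−23.71), Cdk9 (−23.45), Csrp2 (−23.37) and Setdb1 (−23.57). Their standard errors ran from 2.54 for Hpd to 3.51 for Pfdn1. None of the 9 was called in the authors' deposited table. There were 19 genes past the test of the difference with an immunoprecipitate log2 fold change beyond 15 in size, 0 of them called by the authors, and the lowest adjusted p among the 12 with a value was 0.115 in the authors' deposited table. Without such fold changes 178 genes passed in place of 200.

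Large falls of thinly covered features were weighed as a pattern. The signs in the input argue against a lower RNA level of the gene in knockout liver as the whole cause. Of the 50 protein-coding genes called lower, 46 were measured there, with a median of −0.028 and 20 above 0. Input fold changes are shrunken and given per gene, so neither the size of a fall nor a fall of single transcripts can be judged. Few reads per feature may contribute: falls beyond −5 made up 24.1% of protein-coding features at means of 10 to 20 and 2% at 100 and above, a ratio of 12.03. That leaves open why falls outnumber rises, since 10.2% of the features at means of 10 to 20 lay above 5. Scaling bears on this: across all features, calls from fold over standard error went from 213 higher and 606 lower to 284 and 376 on centring. A loss of antibody binding from weakly covered RNAs was not tested.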

How the results depend on the processing

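Alternatives on the statistic, on 1 feature per gene or family, on repeated or extreme fold values, on gene naming, on the authors' calls at a mean of at least 50, on leaving out Fto, on the turned direction and on Sm-class against U6-class copies at a mean of at least 10 were chosen after seeing the data; the others were planned. No paired analysis was possible because the tables hold no values of single replicates, and for the same reason leaving out replicates, other splits of the samples, another normalization and a second count tool were not run. Depth is unknown, and most immunoprecipitate features had a mean under 10. The planned comparison of snRNA genes with and without copies was not run in the immunoprecipitate, where names are those of families.

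Of the comparisons, 38 alternatives kept the call or a count within 1.5 times, 4 raised and 13 lowered a call or a count beyond that, and 1 reversed; of the named features, 20 moved by less than their standard error on centring and 7 by more, with none changing sign. The immunoprecipitate count of 110 became 204 and 25 at thresholds of 0.1 and 0.01, 34 adjusted over all features, 27 for the authors' own calls at a mean of at least 50 and 33 when the adjustment was redone over features at that mean (23 higher, 10 lower), 819 from fold over standard error (213 higher, 606 lower), 660 when those folds were also centred (284 higher, 376 lower), and 62 with 1 feature per gene or family (2 higher, 60 lower). The input count of 5 became 3 at a threshold of 0.01. Turning the immunoprecipitate sign kept the number of differences between the tables (206) but not their direction (166 higher, 40 lower against 44 and 156). The 200 differences became 5 at a minimum mean of 50 and 424 with none. The Sm-class median of 0.27 in the input lost its call at a correlation of 0.1, and genes with their own symbol gave −0.34; the cause was not tested. Immunoprecipitate lists past the test went from 3 to 1 at correlations of 0.05 and 0.1 and with ranks, and to 4 with features named through gene identifiers, where xenobiotic enzymes passed. Input lists went from 10 to 4 and 2 at those correlations, to 7 with ranks and to 9 without Fto.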

Other observations

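The tests of snRNA abundance, scaling and shared reads, and the comparison of U3 and U8 with other snoRNAs, were all chosen after the results were seen, and the criterion of the U5, U11 and U12 test was changed after its value was known.

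Among snoRNAs, U3 and U8 stood apart from the rest in the immunoprecipitate. Both act in ribosomal RNA processing and, unlike most snoRNAs, are transcribed from genes of their own with a cap of their own. All 9 of their copies with a mean of at least 10 lay above 0, with a median of 2.78, while the 193 other snoRNA features had a median of −1.18 and 52 above 0, in the authors' deposited table. None of the 9 copies was called there. U8 in the input was at −0.02 in the authors' deposited table.

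Other small RNAs went in different directions without calls beyond those already given. In the immunoprecipitate the 10 copies of 7SK, which holds the elongation factor P-TEFb, had a median of −2.09, and the 5S rRNA features one of −2.87, in the authors' deposited table. Y RNA had a median of −0.12 before and 0.70 after centring, and the telomerase RNA stood at 0.93 in the authors' deposited table. The input medians were 0.11 for 7SK and 0.15 for Y RNA in the authors' deposited table.

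The rise of Sm-class snRNAs in the immunoprecipitate was weighed against technical causes and RNA level. A scaling shared by all features is argued against by U6-class copies, which lay 3.67 below Sm-class copies at a mean of at least 10. U6-class copies are thinly covered, with no mean above 203 against up to 34539 for U1. They therefore cannot judge a shift that depends on the mean. Well covered RNAs outside the Sm class argue against such a shift at their means. The 100 protein-coding features at means of 100 and above had a median of −0.69. Copies of 7SK at means from 1619 to 2294 lay between −2.91 and −1.83, while U12 stood at 3.36 at a mean of 1686. U3 and U8 did rise, with their most abundant copies at means of 1164 and 2667. For the most abundant U1 copies the question stays open. Shared reads do not account for U4atac, which has 1 copy in the table and stood at 3.45. Copies outside the table were not examined, and U4atac does not settle the matter for U1. A higher RNA level stays open: U1 copies had an input median of 0.40 on a shrunken scale. U5, U11 and U12 had a pooled median of 3.34 in the immunoprecipitate, where the U11 median alone was 1.78. Their input values were below 0, with an upper 95% bound as high as 0.45. Earlier criteria for that last test, 1 with the bound doubled to 0.90 and 1 set against the size of the Fto change, counted against RNA level but rested on assumptions about the shrinkage and were dropped. A gain of m6Am next to the cap without Fto may contribute, as an untested hypothesis that needs the immunoprecipitate fold to be knockout over wild type; read the other way, Sm-class snRNAs would be lower in the knockout.

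For U3 and U8 a candidate explanation is that snoRNAs with a cap of their own rise together. It does not extend to every capped RNA, since U6, with another kind of cap, had a median of −0.80. Their median lay 3.96 above that of the other snoRNAs (exact rank test p = 1.30e-08, with copies that are not independent), but the family was singled out for its values, so the test decides nothing. A test on U13, written before its value was looked for, could not be run because U13 was not analysed here. No technical explanation was tested for this pattern.

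Values repeated across the immunoprecipitate table. There were 842 features at a log2 fold change of −0.82 and 270 at 0.14, within 0.0002, with 0 of either called, in the authors' deposited table. All values were shared with another feature for 1870 features, so counts of features exceed counts of independent measurements.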
